A study of Homo sapiens with 9 samples.

How the data were processed

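Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where 2 related DEAD-box RNA helicases, DDX5 and DDX17, were found on chromatin in NTERA2 cells. NTERA2 is a human embryonal carcinoma line that stays pluripotent in standard culture and forms neural derivatives under retinoic acid. Per the labels' protocols, the differentiated cultures were seeded at low density and kept in 10 uM retinoic acid for 14 days. The same protocols name a commercial kit for shearing the chromatin, an antibody against each helicase and a commercial kit for preparing libraries from small amounts of DNA. The 9 libraries fall into 3 groups of 3, which are DDX17 in undifferentiated cells, DDX17 in differentiated cultures and DDX5 in differentiated cultures. The label of each library gave its group and its replicate number. DDX5 in undifferentiated cells belongs to an earlier series and was not analysed here.

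Per the submitters' processing notes, reads were handled with CASAVA 1.8.2 and coordinates refer to human genome build hg19. The aligner, the treatment of duplicate reads and the control library are not given in the sources used here. The authors deposited 1 peak list per library, with the position of each peak and a score. Peaks carry names that the peak caller MACS gives, and no header states the scale of the score. The lowest score in the lists was 40, which would be a p of 0.0001 on the scale that MACS uses, 10 times the negative log10 of p, so the deposited score was read on that scale and used only to rank, filter or describe peaks within their own list. The authors also deposited 1 list per group of intervals found in triplicate, without a score. Their intervals are peaks of the replicate 1 list that overlap a peak in each of the other lists of the group, as a comparison of the lists showed. The lists hold no read counts, so the sequencing depth of each library is unknown, and a peak missing from a list is a peak not called, not a place shown to be unbound.

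All 9 lists were joined into 1 set of 81240 regions by merging peaks that overlap by at least 1 bp. A region counted as a consensus region of a group when all 3 of its libraries had a peak in it, and as found only in 1 group when it was a consensus region there and no library of the group it was compared with had a peak. The number of peaks and the median peak width per library were compared with a two-sided exact permutation test of the difference in means, for which 3 libraries against 3 give 20 assignments and a smallest p of 0.10. Similarity of lists was measured by the Jaccard index, the base pairs shared by 2 lists divided by the base pairs covered by either, and its mean within groups minus its mean between groups was tested one-sided over all 280 ways of dividing 9 libraries into 3 groups of 3. Overlap of consensus regions was set against 1000 random placements of the regions of 1 group on the same chromosomes, one-sided, with a smallest p of 0.001. Chromosome lengths were taken as the last base of any peak, and assembly gaps were not left out, since no genome of build hg19 was used here.

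These tests, their settings and most of the alternative settings were chosen before the data were examined. The text names regions by a rule from that time, the 10 consensus regions of each group with the best mean rank of the score within their lists, and the 10 best regions found only in 1 group for each direction of each comparison. Others singled out in the text were chosen after their values were seen. The planned annotation of regions with genes, the tests of fixed gene lists, the genomic classes and the sequence content needed gene models or sequence of build hg19. The gene table used here has the coordinates of another build, GRCh38, so none of its positions were set against the peaks and regions are given by their coordinates alone, counted from 1.

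Several measures were added after the data were seen. Peaks narrower than 70 bp were counted separately, because many DDX5 peaks were that narrow. Regions within 1 Mb of the widest interval without any peak on each chromosome, which on most chromosomes falls at the centromere, and those on unplaced contigs, chromosome Y or the mitochondrial genome were counted as high-copy regions, because such sequence is repeated in the genome or abundant in the cell. For chromosomes 12 and 7 the part before that interval is called the short arm and the part after it the long arm. The genome was divided in the same way into 44 chromosome parts of at least 10 Mb, although on chromosomes 13, 14, 15 and 22 the interval lies away from the centromere. The peak density of each part was divided by the median over the parts of its library. Overlaps were also set against regions moved by 10 to 100 kb to either side, which keeps dense stretches of the genome dense. Confidence intervals of shares are 95% Wilson intervals and cover counting error only.

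The labels describe triplicates without saying whether they came from separate cultures. The p-values of tests that permute libraries therefore measure the spread between these libraries, which may be technical. Those of the placement and Fisher tests are over regions and measure no spread between libraries. Lists 1 and 2 of DDX17 in undifferentiated cells were identical in the coordinates of every overlapping peak, and were therefore counted as 1 sample in the means, SDs and n of that group. The lists of the other groups, in which no pair was identical throughout, were counted as 3 samples each, which rests on the labels alone. Exact coordinates were also shared by up to 66.4% of overlapping peaks within those groups. For lists 1 and 3 of undifferentiated DDX17 the share was 68.7%, against at most 3.11% between groups. Shared reads were not tested for these pairs, so SDs, n and p-values may treat the lists as more separate than they are. Counts of consensus regions use all 3 lists as planned, and leaving out list 1 or list 2 gives the count with that pair taken once.

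Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and matplotlib 3.10.9 for the figures. The code was tested on simulated peak lists with 6000 true consensus regions per group, of which it recovered 100% with 0% false regions, and with 400 regions shared by all groups, where the overlap above that of random placement was 99.8% of them in the DDX17 comparison and 99.4% in the comparison of the helicases. Of 100 pairs of independent simulated lists, 1% had a placement p at or under 0.05. The simulated peaks were placed at random along chromosomes, as the placement test assumes, and true regions were put in all 3 lists. These figures therefore check the code and not how the tests behave with clustered peaks.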

Results

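Binding of the RNA helicase DDX17 to chromatin was measured by ChIP-seq in NTERA2 cells before retinoic acid and in the neural cultures obtained after 14 days of 10 uM retinoic acid, and that of DDX5 in the neural cultures only. Both helicases unwind RNA and take part in transcription, splicing and microRNA processing. The lists of DDX17 peaks from undifferentiated cells held 14046, 14087 and 14012 peaks, those of DDX17 from differentiated cultures 17322, 17002 and 16316, and those of DDX5 from differentiated cultures 23906, 23788 and 21551. The sequencing depth behind these lists is unknown.

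The 3 groups had largely separate peak sets. Pairs of libraries of the same group had a mean Jaccard index of 0.468, with a range of 0.345 to 0.658 over 9 pairs, while the 27 pairs from different groups lay between 0.0252 and 0.0489 with a mean of 0.0374. The difference of 0.431 was the largest of the 280 divisions of the 9 libraries into groups of 3, and the highest of the others was 0.215 (exact permutation p = 0.0036, one-sided, the smallest possible). These figures take lists 1 and 2 of DDX17 in undifferentiated cells, the pair with the index of 0.658, as separate libraries. Leaving out either of them gave a difference of 0.420, with the same p in that test. All 11165 peaks of list 1 of DDX17 in undifferentiated cells that overlapped list 2 had the same start and end there, 3337 of them with the same score, whereas list 3 shared the exact coordinates of 4786 of the 6971 overlapping peaks of list 1. Exact coordinates were also shared by 66.1% to 66.4% of overlapping peaks between the DDX17 lists of differentiated cultures, where lists 1 and 2 had 478 peaks (7.07% of the identical ones) with the same score as well and the other pairs 4 each, and by 9.94% to 50.7% between the DDX5 lists, against at most 3.11% between groups.

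**Figure D1:**
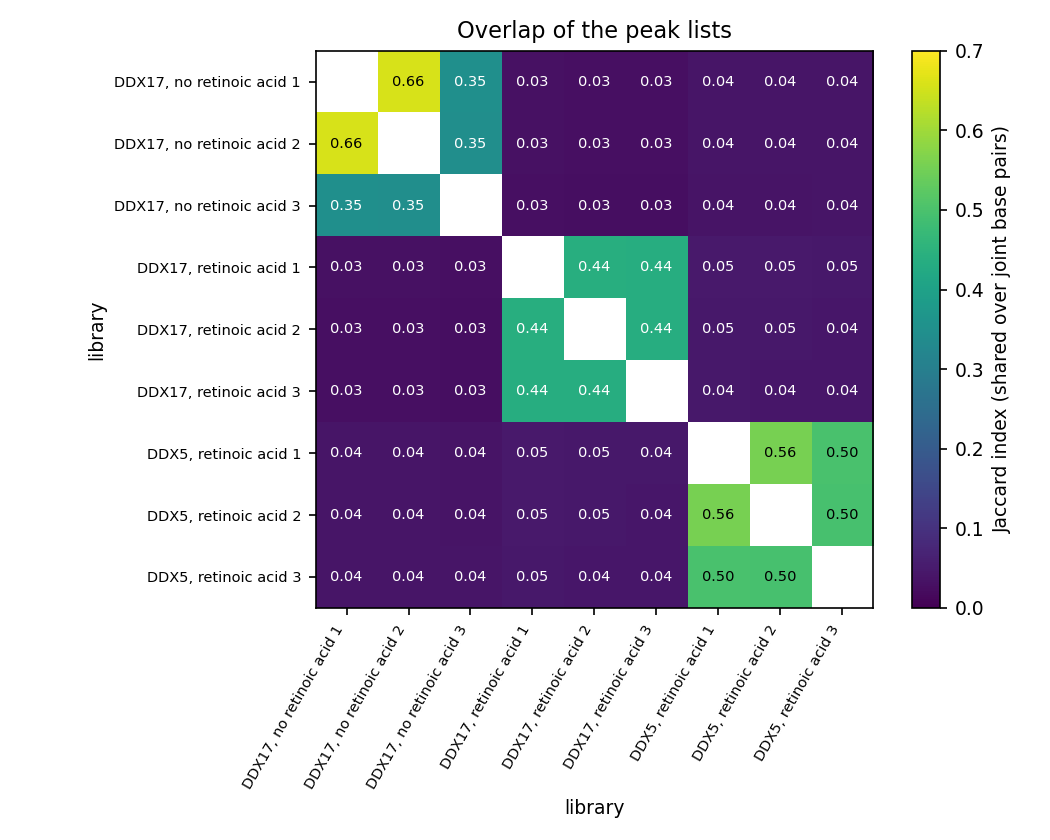
Jaccard index of each pair of the 9 peak lists, with libraries on both axes and colour giving the shared over the joint base pairs. The 9 pairs within groups lie between 0.345 and 0.658 and the 27 pairs between groups at or below 0.0489.

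The first comparison asked where DDX17 was found before and after neural differentiation. DDX17 peaks were called at mostly different places in the 2 states. All 3 libraries of a group had a peak in 6005 regions in undifferentiated cells and in 7577 regions in differentiated cultures. These were 26.1% and 27.0% of the regions called in any library of the group, so most regions were not called throughout their own group. Of these consensus regions 260 were the same, which is 4.33% of the first set and 3.43% of the second. In undifferentiated cells 5584 consensus regions had no peak in any DDX17 library of the differentiated cultures, and 7138 were found only after differentiation. The 260 shared regions were still 18.1 times the 14.3 ± 3.003 (SD over 1000 random placements) that chance gave (permutation p = 0.001, one-sided, the smallest possible). Set against regions moved by 10 to 100 kb the overlap was 8.64 times a mean of 30.1.

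Most of the DDX17 regions found in both states lay in high-copy sequence. Of the 260 shared regions, 142 (54.6%, 95% interval 48.5% to 60.6%) lay near a centromere-like peak-free interval, on an unplaced contig, on chromosome Y or in mitochondrial DNA, against 82 of the 5584 regions found only before differentiation (1.47%) and 448 of the 7138 found only after it (6.28%). Fisher's exact test gave two-sided p values of 4.85e-151 and 6.46e-91 for these contrasts, over regions, which are not independent replicates. Near the centromere of chromosome 16 lay 45 shared regions and near that of chromosome 10 lay 26. Bases 46427311 to 46428167 of chromosome 16 and bases 58777061 to 58779377 of chromosome 6 were among the 10 best regions of DDX17 in differentiated cultures and had a peak in all 9 libraries. A contig that carries a copy of the ribosomal RNA gene repeat, chrUn_gl000220, held the 2 best DDX17 regions after differentiation, at bases 117827 to 125419 and 126763 to 130796, and both were also called in all 3 libraries of each other group.

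The 3 best DDX17 regions that had no peak after differentiation lay in a tight cluster on the long arm of chromosome 5. All 3 undifferentiated libraries had 4 peaks within 6.97 kb, at bases 139930080 to 139930502, 139930647 to 139930825, 139931551 to 139931777 and 139936723 to 139937050. The first had the authors' scores of 2602 to 2684, the third 1132 to 1232 and the fourth 682 to 707. No library of the differentiated cultures, for either helicase, had a peak within 20 kb of the first region. Whether these blocks match exons, as DNA copied from a spliced transcript, such as the insert of a plasmid, would, was not tested, because no gene models of build hg19 were used here, so their scores do not by themselves show binding of DDX17 to this stretch of chromatin. Another undifferentiated region, at bases 1639643 to 1640433 of chromosome 12, had scores of 238 to 299, and one on chromosome 2, at bases 26407084 to 26407976, had 215 to 257. Both were absent from the DDX17 lists of differentiated cultures but called in all 3 DDX5 lists. Of the 10 best regions found only in undifferentiated cells, 5 had a peak in all 3 DDX5 libraries, against 316 (5.66%) of all 5584.

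**Figure D2:**
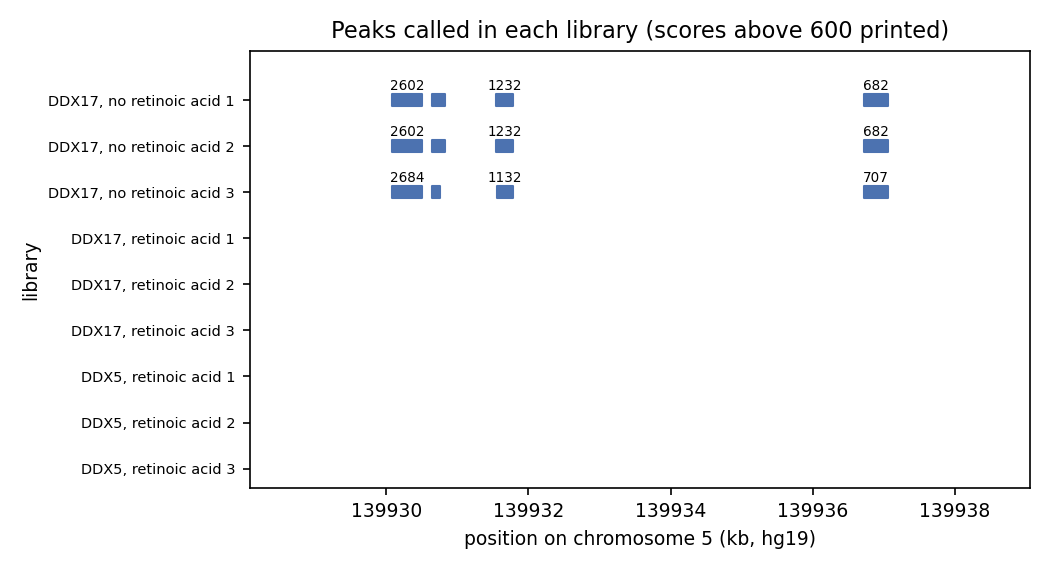
Peaks of the 9 libraries, 1 row each, over a stretch of chromosome 5 (horizontal axis, position in kb, hg19), with bars drawn to scale and the highest scores printed. The 3 DDX17 libraries of undifferentiated cells each have 4 peaks there and the 6 libraries of differentiated cultures have 0, and whether the blocks are exons of copied DNA was not tested.

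The 10 best DDX17 regions found only after differentiation all had a peak in the 3 DDX5 libraries as well, but of all 7138 such regions only 480 (6.72%) did. The best of them was at bases 64953825 to 64954309 of chromosome 7, with scores of 322 to 432, followed by bases 89846353 to 89847051 of chromosome 2, with 312 to 381. Bases 33871226 to 33871767 and 33872166 to 33872699 of chromosome 16 came next. Of these 10 regions, 4 lay within 1 Mb of a widest peak-free interval. The named chromosome 16 regions lay outside that limit, before an interval that starts at base 35279634. Another of the 10 was at bases 16860869 to 16861233 of chromosome 22, where the interval lies away from the centromere. The limit therefore does not show that the other regions lie outside high-copy sequence.

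DDX17 lists from differentiated cultures were longer and their peaks slightly wider. They held 16880 ± 514 peaks (SD, n = 3) against 14039 ± 38.5 (SD, n = 2, lists 1 and 2 counted as 1 sample), a ratio of 1.20. Median peak width was 135.3 ± 0.577 bp (SD, n = 3) against 125.5 ± 0.707 bp (SD, n = 2). Every list of 1 state lay apart from every list of the other in both measures, and the two-sided exact permutation test gave p = 0.10, the smallest that 3 against 3 libraries, or 3 against 2, can give. Without replicate 3 of the undifferentiated group, its consensus regions numbered 11097 and those found only there 10505, since the 2 remaining lists share their peak coordinates.

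Part of the additional DDX17 peaks lay on the short arm of chromosome 12, whose gain is typical of the germ cell tumours from which lines such as NTERA2 come. After differentiation this arm held 26.8 ± 0.918 DDX17 peaks per Mb (SD, n = 3), 4.03 ± 0.123 times the density of the long arm. In undifferentiated cells the ratio was 1.14 ± 0.0659 (SD, n = 2). DDX5 lists of differentiated cultures had a ratio of 3.11 ± 0.195 (SD, n = 3), which was 1.20 ± 0.0759 in the best 50% of each list by score, where the DDX17 lists had 2.84 ± 0.168 (SD, n = 3) after and 1.14 ± 0.194 (SD, n = 2) before differentiation. Of the DDX17 regions found only after differentiation 444 lay on this arm, which is 6.22%, against 104 (1.86%) of those found only before. The two-sided exact permutation test of the ratio between the DDX17 groups, with 3 libraries each, gave p = 0.10, the smallest possible, and the same with lists 1 and 2 counted as 1 sample. The distribution of DDX17 peaks differed over much of the genome, not on this arm alone. Relative to the median part, 33 of 44 chromosome parts had the 3 DDX17 samples from after differentiation all above or all below the 2 from before it, with lists 1 and 2 counted as 1 sample, where 20% would be expected by chance. Of the 44, 25 were denser after differentiation and 19 less dense. The DDX5 and DDX17 lists of differentiated cultures were separate in the same way in 40 of the 44 parts, where 10% would be expected by chance. Such separation is therefore not particular to differentiation. The log2 ratio, after over before, was 1.78 for the short arm of chromosome 12. It was higher only for the part of chromosome 21 before its peak-free interval, at 2.39. That part is 11.2 Mb long and held few peaks, 0.715 per Mb before and 3.87 after differentiation (means of 3 lists). It was 0.91 for the short arm of chromosome 7, 0.83 for the long arm of chromosome 1, −0.92 for the long arm of chromosome 17 and −0.89 for the short arm of chromosome 19. Leaving out the short arm of chromosome 12, the DDX17 lists differed by 2171 peaks on average, against 2832 with it, over all 3 lists of each group.

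**Figure D3:**
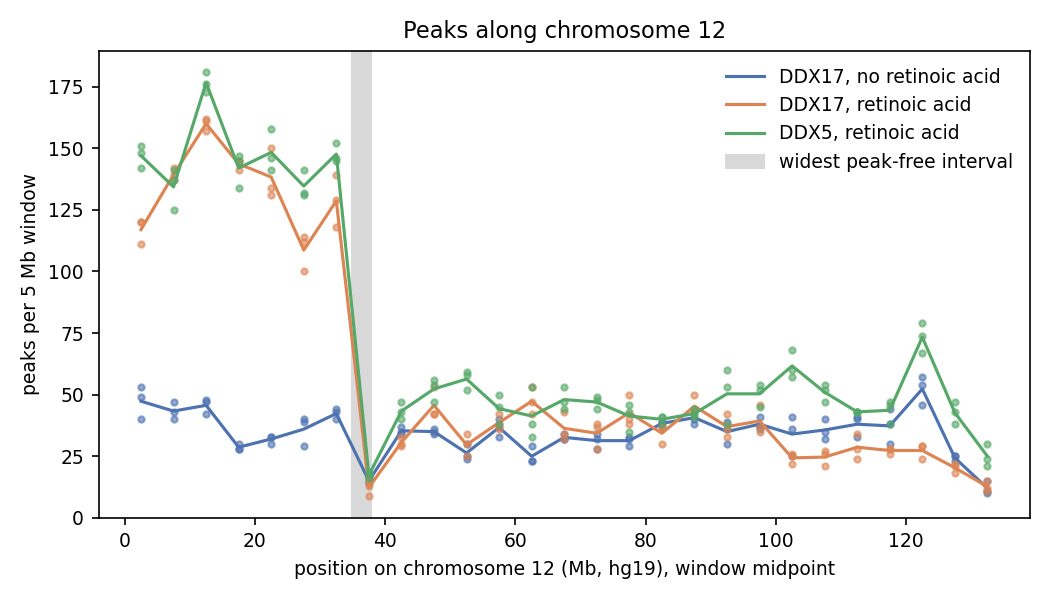
Peaks per 5 Mb window (vertical axis) along chromosome 12 (horizontal axis, window midpoint in Mb, hg19), with points for libraries and lines for group means. In the short arm, left of the shaded peak-free interval, all 6 libraries of differentiated cultures have at least 100 peaks in each full window, while the libraries of undifferentiated cells have at most 53.

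The second comparison asked whether the 2 helicases were found at the same places in differentiated cultures. DDX5 had 13008 consensus regions, 37.9% of the regions called in any DDX5 list, and DDX17 had 7577. Both sets held 706 of these regions, which is 5.43% of the DDX5 set and 9.32% of the DDX17 set. Counting only peaks and regions that overlap by at least 50% of each other's length, 337 were shared, which is 2.85% and 4.62%. DDX5 alone had a peak in 11753 regions, where no DDX17 library of these cultures had one, and DDX17 alone in 6561. The shared number was 31.3 times the 22.5 ± 4.24 (SD over 1000 random placements) expected by chance (permutation p = 0.001, one-sided, the smallest possible), and 8.71 times the mean of 81.0 for regions moved by 10 to 100 kb. With only peaks of at least 70 bp the regions of DDX5 alone numbered 6881, and with the same number of best peaks from each list 6456.

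Regions held by both helicases were again concentrated in high-copy sequence, where 414 of the 706 lay (58.6%, 95% interval 54.97% to 62.22%). Of the regions of DDX5 alone 194 (1.65%) lay there, and of those of DDX17 alone 156 (2.38%). The shared set included 103 regions near the centromere of chromosome 16, 76 near that of chromosome 10 and 61 near that of chromosome 7. Bases 42392340 to 42395090 and 42395116 to 42397336 of chromosome 10 were among the 10 best regions of both helicases. Of the 10 best DDX5 regions, 9 had a peak in all 9 libraries. In mitochondrial DNA, 8 regions between bases 1 and 8768 were called in all 9 libraries.

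The 4 best regions of DDX5 alone were also DDX17 regions before differentiation. Bases 33721741 to 33722606 of chromosome 1 had DDX5 scores of 445 to 522, bases 1359272 to 1360279 of chromosome 16 had 399 to 505, bases 26111286 to 26111963 of chromosome 12 had 401 to 434 and bases 2161520 to 2162296 of chromosome 12 had 355 to 411. These 4 regions had a peak in every DDX17 library of undifferentiated cells and in 0 of the 3 from differentiated cultures. In all, 6 of the 10 best regions of DDX5 alone were called in the 3 undifferentiated DDX17 libraries, against 316 (2.69%) of all 11753. Others were narrow and seen with DDX5 only, such as the 75 bp at bases 157081203 to 157081277 of chromosome 2 and the 62 bp at bases 76528882 to 76528943 of chromosome 4. The 10 best regions of DDX17 alone were 58 to 364 bp wide. First among them were 59 bp at bases 84166566 to 84166624 of chromosome 16, with the authors' scores of 188 to 207, and 85 bp at bases 70965064 to 70965148 of the same chromosome, with 179 to 207.

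DDX5 lists were longer than DDX17 lists from the same kind of culture, with 23082 ± 1327 against 16880 ± 514 peaks (SD, n = 3 each), and their median peak width was smaller, 88.3 ± 7.23 bp against 135.3 ± 0.577 bp. The lists did not overlap in either measure, and the two-sided exact permutation test gave p = 0.10 for each, the smallest possible with 3 libraries against 3. The excess of DDX5 peaks consisted of narrow ones. Peaks under 70 bp made up 38.8% ± 3.90 of the DDX5 lists and 3.93% ± 0.186 of the DDX17 lists (SD, n = 3 each). Of peaks of at least 70 bp, DDX5 lists held 14156 ± 1683 and DDX17 lists 16217 ± 507, so the direction of the difference turned. In list 1 of DDX5, 2113 peaks carried the same score of 115.39, with a median width of 55 bp.

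**Figure D4:**
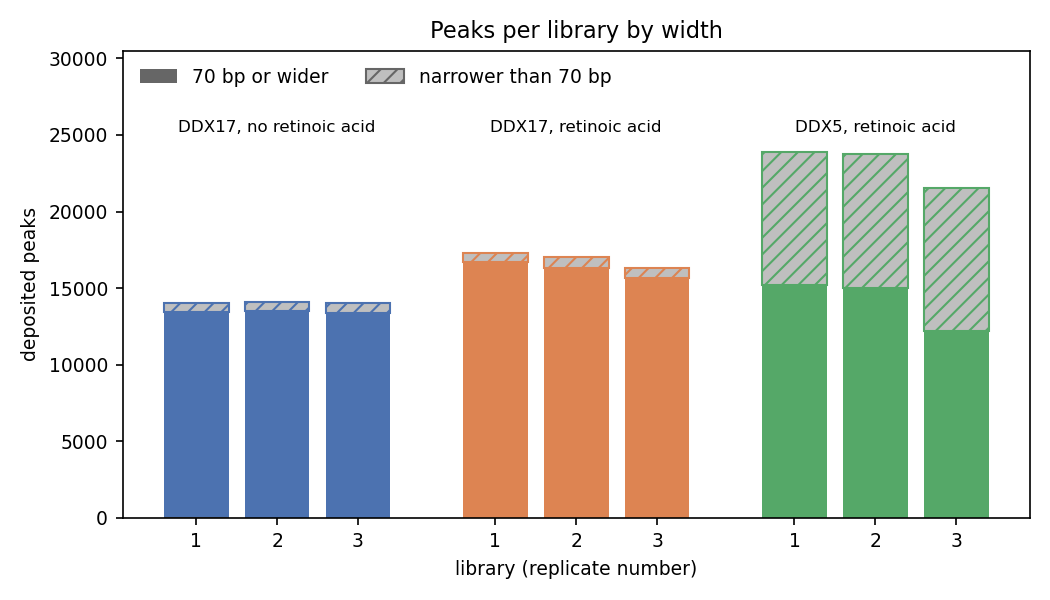
Number of deposited peaks (vertical axis) in each of the 9 libraries (horizontal axis, replicate number by group), with solid bars for peaks of 70 bp or wider and hatched bars for narrower ones. The DDX5 lists are the longest in all, but their solid bars, 12215 to 15215 peaks, stay below those of DDX17 after retinoic acid, 15672 to 16675.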

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

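The alternatives with peaks of at least 70 bp, without high-copy regions, with regions moved by 10 to 100 kb, with replicate 1 lists alone, without the short arm of chromosome 12 and with lists 1 and 2 of undifferentiated DDX17 counted as 1 sample, and those of the arm ratios, were chosen after seeing the data. The overlaps stayed above chance, the similarity within groups stayed above that between groups, and peak widths kept their direction, under each alternative run. With only peaks of at least 70 bp, the difference in peaks between DDX5 and DDX17 reversed to −2061, consensus regions of DDX5 numbered 7819 and regions of DDX5 alone 6881, since narrow peaks make up much of the DDX5 lists. The short to long arm ratio of chromosome 7 in undifferentiated cells reversed to 0.989 in the best 50% of each list, from 1.05 (means of 3 lists, 0.971 with lists 1 and 2 counted as 1 sample). Those after differentiation were 1.15 for DDX17, from 1.56, and 1.10 for DDX5, from 1.48. For DDX17 most of the difference on chromosome 7 thus lay in peaks of lower score. In the DDX5 lists narrow peaks score high, and with peaks of at least 70 bp the DDX5 ratio was 1.64, so the same cannot be said for DDX5. The cause was not tested.

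Region counts moved by more than 1.5 times in several, though not all, of the settings that take more or fewer peaks or ask for a larger overlap. The overlap of DDX5 and DDX17 was 706 as planned, 337 with a reciprocal overlap of at least 50%, 1204 with 2 of 3 libraries, 333 with the best 50% of each list, 450 with the same number of best peaks and 1486 with replicate 1 lists alone. For DDX17 these were 260, 197, 476, 188, 241 and 548. With peaks in at least 2 of 3 libraries, consensus regions numbered 12883 for DDX17 before differentiation, 14552 after it and 21215 for DDX5. Regions found only in 1 group then numbered 13914 after and 12229 before differentiation for DDX17, and 19512 for DDX5 alone and 13034 for DDX17 alone. With the best 50% of each list by score, the same quantities were 2841, 3007 and 5669, then 2742 and 2558, and 5160 and 2494. The same number of best peaks from each list gave 6456 regions of DDX5 alone. Among the alternatives that keep every library, 63 other values of the planned results kept their direction and side of the threshold or stayed within 1.5 times.

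Leaving out each library in turn, consensus regions ranged from 6880 to 11097 for DDX17 before differentiation, where only the count without replicate 3 was over 1.5 times the main one, from 9745 to 10113 for DDX17 after it and from 15313 to 16547 for DDX5. Regions found only before differentiation ranged from 5610 to 10505 and only after it from 7156 to 9591, those of DDX5 alone from 11848 to 15053 and of DDX17 alone from 6599 to 8878. Overlaps ranged from 269 to 332 and from 737 to 810.

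No pairing of the libraries by replicate number was seen in the scores, which does not show that same-numbered libraries came from separate cultures. Over regions seen in both groups, deviations from the group means of same-numbered libraries correlated between −0.0321 and 0.0262. With the replicate number as a block, the differences in peaks remained 2832 and 6202, with an exact p of 0.25 (smallest possible with 3 pairs), the regions found only in 1 group were the same by construction, and the similarity difference was 0.431. The planned tests of target genes, gene lists, genomic location, sequence and placement within gene bodies were not run, because no gene models or sequence of build hg19 were used here.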

Other observations

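The tests below on identical peak coordinates between groups, on the best 50% of the DDX17 lists for chromosome 12, on copies of that arm and on broad regions were chosen only after the results were seen. Outside high-copy sequence, broad regions, whose peaks averaged at least 300 bp over the 3 lists of a group, were shared to different degrees between the groups, and those of DDX5 in differentiated cultures most often with DDX17 in undifferentiated cells. Of 72 broad DDX5 regions, 43 (59.7%, 95% interval 48.2% to 70.3%) were consensus regions of DDX17 before differentiation and 9 (12.5%, 6.72% to 22.1%) were consensus regions of DDX17 after it. Of 73 broad DDX17 regions of undifferentiated cells, 36 (49.3%) were consensus regions of DDX5 and 13 (17.8%) of DDX17 after differentiation. Of 80 broad DDX17 regions of differentiated cultures, 25 (31.3%, 22.2% to 42.1%) were consensus regions of DDX5, against 2.16 on average for regions moved by 10 to 100 kb. Of the same 80, 2 (2.5%) were consensus regions of DDX17 before differentiation. The helicases therefore also shared broad regions in the same kind of culture. For DDX5, 46 to 48 of the 72 broad DDX5 regions had a peak in each DDX17 library of undifferentiated cells and 9 to 12 in each of the differentiated cultures. Moved by 10 to 100 kb, the DDX17 regions overlapped 0.175 and 0.782 broad DDX5 regions on average. Narrower DDX5 consensus regions were shared far less, at 2.43% and 2.32% of 12219 DDX5 regions. Over consensus regions of any width outside high-copy sequence, DDX5 shared 340 regions with DDX17 before differentiation, 36.1 times the mean for moved regions, and 292 with DDX17 after it, 15.6 times. With high-copy sequence included, as planned, the order was the reverse, with 503 and 706.

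Lists 1 and 2 of DDX17 in undifferentiated cells had identical coordinates in 100% of their overlapping peaks. At most 3.11% of overlapping peaks were identical between groups, so peak edges were not fixed by the genome alone across groups. The groups differ in antibody or state and in median peak width, so this test cannot exclude edges fixed within a group. A candidate explanation is that both lists come from the same immunoprecipitated reads, called against different controls. Of the best 50% of list 1, list 2 lacked 601 peaks and list 3 lacked 2869, a ratio of 0.209, which lies between the bounds set beforehand for and against this explanation. It therefore remains open, and no biological explanation was tested.

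Peaks were dense over the whole short arm of chromosome 12 in all 6 libraries of differentiated cultures. Narrow stacked peaks as the cause are excluded by the peaks of at least 70 bp. Their lower group ratio of short to long arm density was 4.12. For DDX17 the ratio was 4.03 in all peaks and 2.84 in the best 50% of its lists, so peaks below the median score do not account for all of it. That test cannot exclude weak peaks, because the median scores of 53.9 to 54.4 lay near the lowest score of 40. For DDX5 the ratio was 1.20 in the best 50% of the lists, where narrow peaks score high, and 2.05 ± 0.148 (SD, n = 3) in the best 50% of its peaks of at least 70 bp, too close to the bound of 2 set beforehand to decide. More copies of the arm in these cultures, or a control library that lacks the copies, may raise the peak density, and the lowest ratio among the 6 libraries was 2.93, but these explanations cannot be told apart without the control reads. An effect of retinoic acid on binding along the arm remains untested.

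High-copy sequence held most regions shared in the DDX17 comparison and in that of the helicases, but only 163 (32.4%) of the 503 shared by DDX5 and DDX17 before differentiation. Without it, 118 regions were still shared by DDX17 before and after differentiation, 19.95 times the overlap of regions moved by 10 to 100 kb. In the comparison of the helicases 292 were still shared, 15.6 times the overlap of moved regions. The stretches counted as high-copy therefore do not account for all of the overlap. Sequence near the centromeres of chromosomes 13, 14, 15 and 22 was not among them, nor were repeats elsewhere, so high-copy sequence as a whole is not excluded. Of the 163 regions called in all 9 libraries, 140 lay in high-copy sequence. Most of the 118 and of the 292 were therefore not called in every library. High-copy regions themselves were often not called in every library. Of 649 high-copy DDX17 regions after differentiation, 448 had no peak in any DDX17 list before it. A missing peak is also only a peak not called, so absence from some libraries does not argue against a high-copy source. Whether the 118 and the 292 reflect binding could not be decided from the lists. The 118 were 2.05% of the DDX17 regions before and 1.70% of those after differentiation outside high-copy sequence.

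Chromosome 7 showed a smaller difference of the same form, with a short to long arm ratio of 1.56 ± 0.0203 for DDX17 and 1.48 ± 0.0543 for DDX5 in differentiated cultures (SD, n = 3 each) and 1.04 ± 0.0149 in undifferentiated cells (SD, n = 2). In the best 50% of each list these ratios were 1.15 ± 0.0637 and 1.10 ± 0.0669 (SD, n = 3 each) and 0.971 ± 0.0772 (SD, n = 2), so the difference for DDX17 was mostly carried by peaks of lower score. Regions found only in 1 group numbered 12722 in the DDX17 comparison and 18314 in that of the helicases, over both directions. In each, 1 of the 10 splits of the 6 libraries, the real one, gave as many, the highest other split gave 39 and 42, and 10 splits are too few for a share under 0.05.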
